A study of Homo sapiens with 18 samples.

How the data were processed

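The series holds 18 samples of human non-small cell lung cancer cells in 6 groups of 3: circRNA, miRNA and mRNA libraries of a control group and of a drug-resistant group. Per the labels, the samples of a group are separate biological replicates and the cell line is not named. Nothing in the labels says which cultures they came from, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, RNA was extracted with TRIzol, miRNA libraries were made with a QIAseq miRNA kit, and the mRNA, lncRNA and circRNA libraries with a stranded total RNA kit that depletes ribosomal RNA, although the molecule label of the mRNA samples is polyA RNA. The submitters' processing notes name hg38 and StringTie without a role. The aligner, the circRNA caller, the miRNA annotation version and any use of molecular identifiers are not given in the sources used here.

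The authors deposited 1 table per assay, each with 1 column per library, and none of the tables holds counts. The circRNA table holds, from its values, RPM by the authors, relative to a library total of 97086177 to 107978443 reads. Every value above 0 in it is a whole multiple of 1 read within a tolerance of 0.05, and the smallest is 2 reads. The deposited mRNA table holds TPM, inferred from the values, whose columns sum to 861701 to 889468, so that the table does not hold all features behind the unit. TPM keeps no depth, so no interval or floor is given for it. The deposited miRNA table holds CPM, and 100% of its values came back as whole reads within the same tolerance. The design fixed before the data were examined assumed counts in all tables. As the values are not counts, limma replaced edgeR as the main test, and edgeR and DESeq2 were run only on reads rebuilt from the RPM and CPM.

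The mRNA table has 17417 entries, of which 220 carry no symbol. Second identifiers of genes shared by the X and Y chromosomes, 18 in number, were left out. In all 17396 genes were used, and 17240 identifiers are protein coding in GENCODE 29. The circRNA table has 11256 circRNAs, 387 of them without a host gene, and the miRNA table has 1206 mature miRNAs. No value column was left without a sample.

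Each assay was compared between resistant and control libraries, 3 against 3, with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, two-sided) on log2(value + pseudocount). The pseudocount was 1 for TPM, 1 for CPM and 0.02 for RPM, and fold changes are on that scale, which understates the change of low genes. Genes needed at least 1 TPM, miRNAs at least 5 CPM and circRNAs a value above 0, each in at least 3 libraries. The Benjamini-Hochberg threshold was 0.05. Fold changes are resistant minus control. The circRNA share was tested with an exact permutation test, whose smallest p in this design is 0.1. The circular-to-linear ratio was tested with limma on the log2 ratio of circRNA RPM summed per host to host TPM, matched by the library name stem, since the planned interaction on counts was not possible.

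Fixed lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, where at least 5 genes or 3 miRNA arms were tested. The gene lists cover EGFR family, PDGF, other receptor tyrosine kinases, ERK-induced transcripts, SLIT-ROBO, mesenchymal, epithelial, lung lineage, squamous and basal, neuroendocrine, fibroblast, endothelial, leukocyte and erythroid markers, cell cycle, apoptosis, interferon-stimulated, antigen presentation, NF-kB and cytokine, NRF2, drug efflux, YAP and TEAD, sterol synthesis, hypoxia and glycolysis, unfolded protein and integrated stress response, p53, mitochondrially encoded oxidative phosphorylation genes and cancer-associated lncRNAs. The miRNA lists cover 21 families, clusters and tissue groups. A list of kidney tubule markers and a list of conserved miRNA families were added after the data were seen.

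Genes named in the text follow a rule fixed before the data were examined. It takes genes past the threshold whose library ranges do not overlap and whose mean is at least 1 TPM (10 CPM for miRNAs), the 8 largest changes in each direction, up to 3 members of each fixed list by size of change, both arms of miR-625, and ROBO2, PDGFB, PDGFRA, PDGFRB and EGFR. For circRNAs it takes the 8 largest in each direction and each tested circRNA assigned to ROBO2, and for the circular-to-linear ratio the 5 largest hosts in each direction. The text does not print every gene the rule takes. Other names were chosen after their values were seen, and the text says so. Each circRNA is identified by its coordinates. The circRNA in the series title is not matched to an identifier in the sources used here, so no circRNA is given that name. XIST, TSIX and Y-linked genes were left out.

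Uniqueness of a gene is the share of 75-base windows of its GENCODE 29 transcripts that occur in no other annotated gene, so unannotated copies are not covered. Scripts were tested on simulated data with 200 known changes per assay, all in features at or above the median control mean of those above 0. For the mRNA comparison limma recovered 89.0% of 100 genes changed 2-fold and 97.0% of 100 changed 4-fold, among 12605 genes run. For miRNA it recovered 84.0% of 94 and 100% of 92, among 494. For circRNA it recovered 13.1% and 62.6% of 99 each, among 7328, with few reads per circRNA. Changes of lower features were not simulated, nor a difference as wide as here, where 81.5% of tested genes were called. Alternatives covered other pseudocounts, filters, scalings, count tests on rebuilt reads, replicate blocks and each library left out in turn. The edgeR (4.0.16) and DESeq2 (1.42.0) fits, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 complete the tools. Intervals and floors cover counting error only.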

Results

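The series asked how osimertinib-resistant lung cancer cells differ in circular RNA, microRNA and mRNA from control cells. Osimertinib inhibits mutant EGFR, and the series title names a circRNA of ROBO2, miR-625-5p, PDGFB and MAPK signalling. Each assay had 3 control and 3 resistant libraries. The circRNA libraries held 79317 to 85973 reads across back-splice junctions in control and 33351 to 42912 in resistant. The miRNA libraries held 654710, 890287 and 1020939 reads in control and 4974783, 4325234 and 5105947 in resistant, so a count of 0 allows up to 2.93 to 4.58 CPM in control and 0.587 to 0.693 CPM in resistant libraries. The mRNA table carries no depth. How the resistant cells were derived, and whether they come from the same cells as the control, is not given in the sources used here. Each fold change therefore compares the libraries as labelled, and differences between unrelated cells, or reads of another species that do not map to hg38, are not ruled out as a source of values at 0 and of falls. Across tested genes, log2 TPM correlated at r = 0.988 to 0.992 between libraries of a group and at 0.666 to 0.683 between groups, where genes are not independent replicates.

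The mRNA comparison asked which genes changed in the resistant cells. ROBO2, a receptor for SLIT guidance ligands (chromosome 3, 75906695 to 77649964, hg38), rose from 1.11 ± 0.150 TPM to 187 ± 12.5 TPM (SD, n = 3), a log2 fold change of 6.47 (SE 0.0928, adjusted p = 3.1e-09). The growth factor PDGFB (chromosome 22, 39223359 to 39244751) rose from 2.05 ± 0.931 to 82.0 ± 15.3 TPM, a log2 fold change of 4.80 (SE 0.244, adjusted p = 8.9e-07). EGFR, the drug's target, rose from 9.63 ± 0.508 to 36.1 ± 4.10 TPM (log2 fold change 1.80, adjusted p = 1.5e-06). The PDGFB receptors stayed below the filter in both groups, with PDGFRA at 0.317 ± 0.140 TPM in control and 0.233 ± 0.0902 TPM in resistant, and PDGFRB at 0.5, 0.45 and 0.13 TPM in control and 0.03, 0.55 and 0 TPM in resistant libraries. Of 13185 genes tested, 4835 were higher and 5914 lower in resistant cells, 81.5% in all, and 83.3% had library ranges that did not overlap, against 10% by chance.

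**Figure D1:**
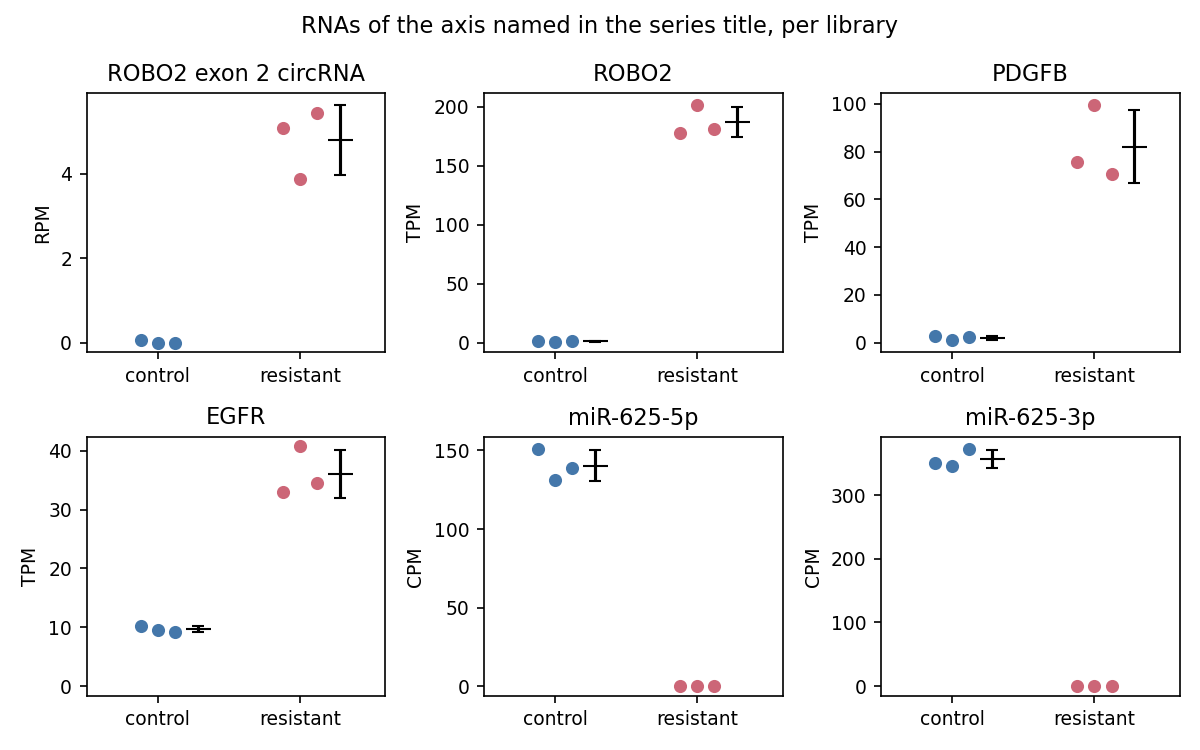
Points are libraries of the control and resistant groups (3 each), with RPM, TPM or CPM on the vertical axis and the mean and SD drawn beside groups in which each library lies above 0. ROBO2 rose from 1.11 to 187 TPM, PDGFB from 2.05 to 82.0 TPM and EGFR from 9.63 to 36.1 TPM, while miR-625-5p fell from 140 CPM to 1 read over the 3 resistant libraries.

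The largest rises included the calcium-binding protein S100A6, listed at 0, 0.63 and 0 TPM in control and between 3989 and 4202 TPM in resistant libraries (log2 fold change 11.76). IGFBP3, which binds insulin-like growth factors, rose from 2.35 ± 0.492 to 9630 ± 2704 TPM. The neuropeptide NTS rose from 0.527 ± 0.391 to 2904 ± 85.4 TPM and the secreted protein VGF from 0.323 ± 0.107 to 1118 ± 250 TPM. TM4SF1 was listed at 0 in each control library and stood at 1573 ± 87.6 TPM in resistant cells. AKR1B10 and AKR1B15, near-identical aldo-keto reductases whose reads the authors' counting could split, had log2 fold changes of 9.83 and 9.80, uncertain for that reason. The aldehyde dehydrogenase ALDH1A1, listed at 0.11, 0.33 and 0 TPM in control, stood at 948 ± 119 TPM in resistant cells. The 8 largest falls were all mitochondrially encoded mRNAs. MT-ATP8 stood at 49446 ± 2584 TPM in control and MT-CO2 at 17829 ± 735 TPM, and both were listed at 0 in each resistant library. Mitochondrially encoded mRNAs made up 17.5% to 18.1% of the table's TPM in the control libraries and 0.00157% to 0.00211% in the resistant libraries. All 13 of them fell (camera adjusted p = 1.3e-08, adjusted p = 0.210 with an estimated correlation). The median log2 fold change of all tested genes was -0.14, and -0.40 once these 13 were left out and the libraries rescaled, with 3883 genes higher and 6998 lower.

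In the fixed lists, the count adjusted over the list alone was the same as that over all genes unless another is given. A member under 1 TPM in each control library could be tested only through the resistant libraries, so the filter set its direction. The same holds the other way for members under 1 TPM in each resistant library. List counts and camera p-values thus rest in part on the filter. None of the 12 lists past the camera threshold kept its call with an estimated correlation. The lowest camera adjusted p with that correlation was 0.210, also that of the 13 mitochondrially encoded mRNAs, all near 0 in resistant libraries. Failing this check therefore neither backs nor excludes a change of a given list. Of 27 NF-kB and cytokine genes measured, 19 were tested, with 18 higher and 1 lower (camera adjusted p = 2.6e-06, adjusted p = 0.210 with an estimated correlation). The interleukin IL6 was listed at 0.41, 0 and 0 TPM in control and stood at 403 ± 67.5 TPM in resistant cells. IL1A rose with a log2 fold change of 7.28, and the lipocalin LCN2, listed at 0 in control, reached 52.7 ± 12.2 TPM. IL6 and LCN2 are among the members whose direction the filter set. Interferon-stimulated genes had 22 higher and 9 lower of 33 (camera adjusted p = 0.00562, adjusted p = 0.229 with an estimated correlation). Among them IFIT3 rose from 0.313 ± 0.0723 to 53.8 ± 5.04 TPM and ISG15 rose to 64.6 ± 11.6 TPM (log2 fold change 4.08). BST2, which tethers virions, fell from 59.0 ± 3.79 to 2.73 ± 0.345 TPM. Antigen presentation genes had 12 higher and 5 lower of 20 (camera adjusted p = 0.0333, adjusted p = 0.307 with an estimated correlation). HLA-DPB1, at 16.8 ± 1.77 TPM in control, was listed at 0 in each resistant library. Reads of HLA genes can be split between near-identical copies.

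ERK-induced transcripts, a readout of MAPK signalling, had 15 higher and 4 lower of 24 (camera adjusted p = 0.00701, adjusted p = 0.210 with an estimated correlation). IL11 rose from 0.327 ± 0.285 to 131 ± 20.5 TPM, the AP-1 gene JUNB from 6.96 ± 0.447 to 112 ± 26.9 TPM and PHLDA1 from 0.640 ± 0.0346 to 20.8 ± 0.714 TPM. EGFR family receptors and ligands had 8 higher and 3 lower of 11 (camera adjusted p = 0.0630). The ligands AREG, from 0.657 ± 0.319 to 36.6 ± 7.32 TPM, and TGFA, from 0.587 ± 0.0987 to 25.2 ± 1.49 TPM, rose, and EREG, listed at 0 in control, stood at 6.08 ± 1.90 TPM. IL11, PHLDA1, TGFA and EREG lay under 1 TPM in each control library, so the filter set their direction. Of the PDGF list 3 of 4 tested members rose and 1 fell, too few for camera. PDGFC rose from 7.35 ± 1.28 to 88.8 ± 7.73 TPM and PDGFA from 11.1 ± 1.33 to 16.8 ± 3.99 TPM (adjusted p = 0.0250, a call that some other settings did not keep). Other receptor tyrosine kinases and ligands had 8 higher and 11 lower of 24, with camera adjusted p = 0.619, and 10 higher and 9 lower after scaling to equal medians. AXL rose from 1.41 ± 0.117 to 118 ± 7.79 TPM and EPHB4 fell from 23.9 ± 1.56 to 1.24 ± 0.170 TPM. In the SLIT-ROBO list 3 of 6 members were higher and 2 lower (camera adjusted p = 0.588). ROBO1, the paralogue of ROBO2, stood between 12.1 and 15.2 TPM in control and was listed at 0 in each resistant library, and SRGAP2 rose from 8.02 ± 1.81 to 44.7 ± 3.30 TPM.

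Mesenchymal markers had 16 higher and 6 lower of 22 (camera adjusted p = 0.0120, adjusted p = 0.489 with an estimated correlation). Fibronectin FN1 rose from 29.7 ± 3.11 to 1211 ± 25.1 TPM, while the collagen COL1A1 fell from 18.9 ± 1.09 to 0.330 ± 0.110 TPM. Epithelial markers had 6 higher and 10 lower of 17 (camera adjusted p = 0.588), with a median log2 fold change of -0.84, a mean of 0.09 and the camera direction down. The tight-junction gene CLDN4 rose with a log2 fold change of 7.75 and the adhesion molecule EPCAM from 0.210 ± 0.118 to 67.5 ± 3.42 TPM. YAP and TEAD targets had 19 higher and 6 lower of 26 (camera adjusted p = 0.00389, adjusted p = 0.210 with an estimated correlation), with ANKRD1 falling from 99.4 ± 11.5 to 1.52 ± 0.434 TPM against the rises of IGFBP3 and AXL. Drug efflux transporters had 11 higher and 1 lower of 14 (camera adjusted p = 0.00136, adjusted p = 0.210 with an estimated correlation). ABCB1, the P-glycoprotein pump, rose with a log2 fold change of 5.77 (adjusted p = 1.8e-08) and the vault protein MVP from 2.50 ± 0.461 to 85.3 ± 13.2 TPM. NRF2 targets had 14 higher and 3 lower of 23 (camera adjusted p = 0.00613, adjusted p = 0.679 with an estimated correlation), with AKR1C3 rising from 2.25 ± 1.58 to 179 ± 34.6 TPM. Control replicate 3 stood apart in this list, with the haem oxygenase gene HMOX1, chosen after its values were seen, at 8.77 TPM in that library and 217 TPM in control replicate 2. Hypoxia and glycolysis genes had 20 higher and 6 lower of 28 (camera adjusted p = 0.00562, adjusted p = 0.229 with an estimated correlation), including the lactate exporter SLC16A3, from 2.10 ± 0.411 to 62.6 ± 14.9 TPM, and CA12, from 3.74 ± 1.33 to 38.0 ± 8.05 TPM. Neuroendocrine markers had 7 higher and 1 lower of 10 (camera adjusted p = 0.0378, adjusted p = 0.377 with an estimated correlation), including the adhesion molecule NCAM1, from 5.80 ± 0.549 to 149 ± 7.38 TPM.

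Cell cycle genes fell, with 30 lower and 6 higher of 40 (camera adjusted p = 0.00473, adjusted p = 0.679 with an estimated correlation). The survivin gene BIRC5 fell from 103 ± 6.86 to 20.8 ± 2.13 TPM, the transcription factor E2F2 from 8.90 ± 0.778 to 1.68 ± 0.145 TPM and the phosphatase CDC25A from 35.7 ± 1.38 to 11.7 ± 1.21 TPM. Several lists did not pass the camera test. Apoptosis regulators had 11 higher and 10 lower of 24 (adjusted p = 0.485), or 10 and 11 without mitochondrially encoded genes. Sterol synthesis genes had 11 higher and 8 lower of 23, with 12 higher adjusted over the list alone and 6 higher and 8 lower without mitochondrially encoded genes (camera adjusted p = 0.485, where fry gave the opposite direction). The unfolded protein and integrated stress response list had 13 higher and 10 lower of 27 (adjusted p = 0.297) and the p53 list 12 higher and 8 lower of 23 (adjusted p = 0.485). Within these lists the caspase inhibitor BIRC3 rose from 2.89 ± 0.842 to 96.7 ± 7.43 TPM, BCL2 from 2.27 ± 0.127 to 40.0 ± 0.651 TPM, GDF15 from 0.973 ± 0.543 to 248 ± 25.8 TPM and the sterol oxidase MSMO1 with a log2 fold change of 2.28. Lung lineage markers had 3 higher and 2 lower of 6 (adjusted p = 0.485), and squamous and basal markers 2 higher and 3 lower of 5 (adjusted p = 0.588), with KRT17 at 33.4 ± 11.2 TPM in control and listed at 0 in each resistant library.

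Markers of other cell types moved in both directions. Of the fibroblast list 5 of 8 tested members fell and none rose (camera adjusted p = 0.0935), with 5 lower and 1 higher at equal medians, and PDPN, at 33.0 ± 4.81 TPM in control, was listed at 0 in each resistant library. Of 12 endothelial markers on the list 2 were tested, and both rose, as ENG did from 0.113 ± 0.0451 to 12.1 ± 1.62 TPM. Of 21 leukocyte markers 3 were tested and rose, among them the macrophage marker CD68, from 0.847 ± 0.124 to 63.2 ± 9.23 TPM. The other members were absent or did not pass the filter. ENG and CD68, under 1 TPM in control, could be tested only through the resistant libraries, so the filter set their direction. Of 2 erythroid genes 1 rose, HBA1, which shares its reads with a near-identical copy, and the only tested member of the lncRNA list, TUG1, fell from 42.7 ± 1.19 to 14.6 ± 0.437 TPM. These lists were too short for camera, apart from the fibroblast list.

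**Figure D2:**
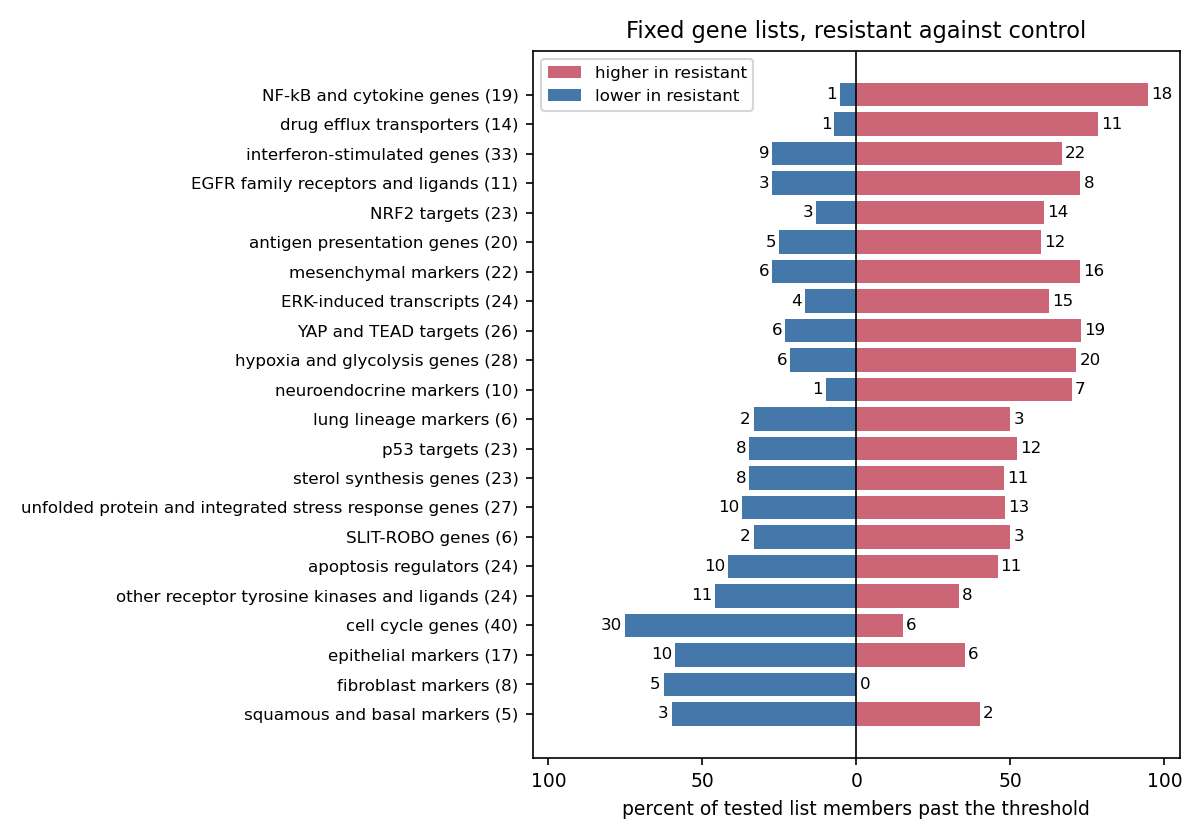
Bars give the percent of tested members of each fixed gene list that were higher (right) or lower (left) in resistant cells, with the number of genes at the bar's end and the number tested in brackets. NF-kB and cytokine genes have 18 higher and 1 lower, and cell cycle genes 6 higher and 30 lower.

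The circRNA comparison asked which circular RNAs changed, with the ROBO2 locus as the one named in the title. The circRNA formed by exon 2 of ROBO2 (chromosome 3, 77098014 to 77098340, 327 bases) stood at 0.0694, 0 and 0 RPM in control and at 4.80 ± 0.819 RPM in resistant cells, a log2 fold change of 7.18 (SE 0.619, adjusted p = 0.000207). A circRNA of exons 3 to 5 (77477414 to 77493382) was listed at 0 in each control library, which in this table means fewer than 2 reads, and had 0.914 ± 0.178 RPM in resistant cells, one of exons 7 to 8 (77546338 to 77550989) 0.410 ± 0.0400 RPM, one of exons 3 to 4 (77477414 to 77481219) 0.119 ± 0.0813 RPM and one of exons 9 to 20 (77557944 to 77602491) 0.104 ± 0.0424 RPM. A pair of circRNAs whose ends match no annotated exon pair went the other way. The one at 76350823 to 76354385 had 0.114 ± 0.0236 RPM and the one at 76311244 to 76354385 had 0.0397, 0.0875 and 0.0289 RPM in control, and both were listed at 0 in resistant libraries. The call of the one at 76311244 was lost after quantile normalization (adjusted p = 0.542). In all, 2 of the other settings did not keep that call, and 1 did not keep the call of the one at 76350823. Of 4970 circRNAs tested, 628 were higher and 2750 lower in resistant cells, with a median log2 fold change of -1.55. A circRNA found in no library of a group could be tested only through the other group, so the filter set its direction. This holds for 2128 found in all 3 control libraries and no resistant one, and for 334 the reverse. Among them are the ROBO2 circRNAs above that were listed at 0 in each library of a group. With at least 10 reads in 3 libraries, a filter that left 1679 to test, 308 were higher and 978 lower. Scaled to equal medians 689 were higher and 2668 lower, and scaled to equal circRNA totals 946 and 2389. Quantile normalization, which makes the distributions alike, gave 1016 higher and 852 lower, with a median of -0.06.

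**Figure D3:**
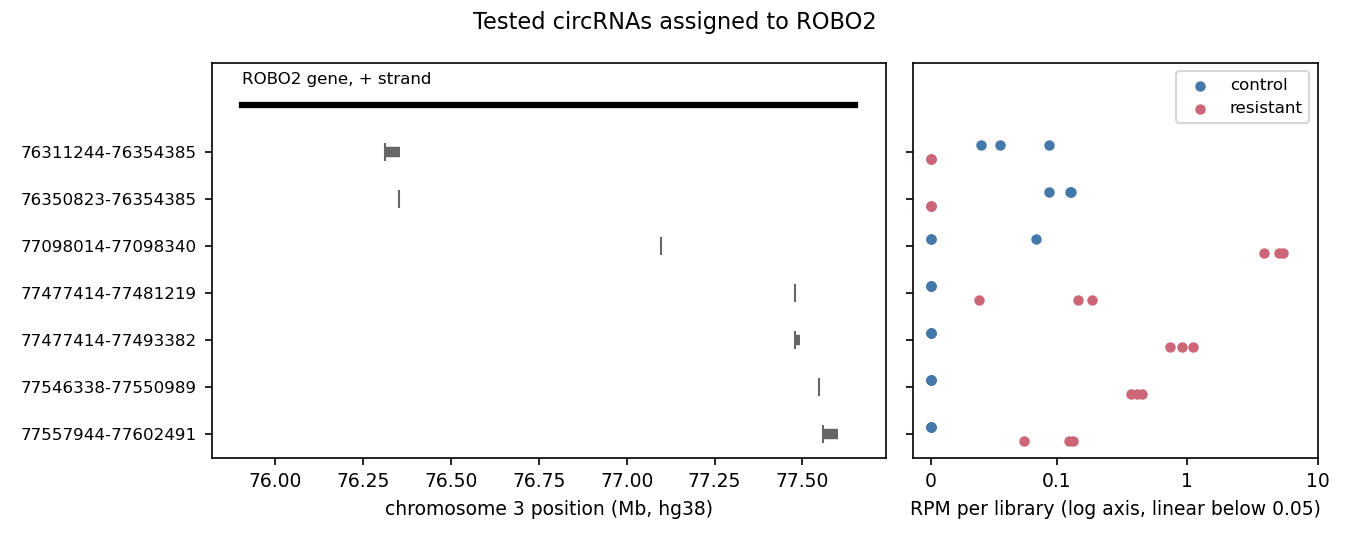
The left panel maps the tested circRNAs assigned to ROBO2 on chromosome 3 (hg38, Mb), and the right panel gives their RPM in each library on a log axis that is linear below 0.05. Those between 77098014 and 77602491 lie higher in the resistant libraries, and those at 76311244 and 76350823 lie higher in the control libraries.

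Outside ROBO2, the largest rises were a circRNA of SDCCAG8 exons 13 to 16, listed at 0 in control and with 1.93 ± 0.218 RPM in resistant cells, and one assigned to TTC28, also listed at 0 in control, with 1.01 ± 0.168 RPM. One of PHLDB2 exons 4 to 6 stood at 0, 0.0486 and 0.0193 RPM in control and 1.81 ± 0.268 RPM in resistant cells. A circRNA of MAP2K5 exons 9 to 13, from a MAPK kinase gene, stood at 0.159, 0.0292 and 0 RPM in control and 2.22 ± 0.445 RPM in resistant cells, and 2 circRNAs of ATP9B that start at exon 5 rose to 1.30 ± 0.192 and 1.16 ± 0.296 RPM. The largest falls were circRNAs of FAM13B exons 8 to 10 (3.23 ± 0.230 RPM in control), XPO1 exons 2 to 4 (2.89 ± 0.227 RPM), GCN1 exons 29 to 31 (2.88 ± 0.256 RPM) and the X chromosome lncRNA FIRRE exons 5 to 10 (2.58 ± 0.0870 RPM), each listed at 0 in the resistant libraries. Those of CTBP1, ECPAS, MED13L and CEP72 also fell. Of all circRNAs 2128 were found in all 3 control libraries and in no resistant one, and 334 the reverse. The summed circRNA level was 808 ± 37.4 RPM in control and 380 ± 66.1 RPM in resistant libraries, a ratio of 0.471 (exact permutation test, p = 0.1, the smallest 3 against 3 allows).

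Circular and linear RNA of the same host were compared to ask which circRNA changes went beyond those of the gene. Of 2685 hosts, 1556 changed in circular-to-linear ratio, 1333 of them with a lower ratio in resistant cells, with a median log2 change of -1.28, and with 397 higher and 922 lower after circRNA totals were made equal. The circular-to-linear ratio of ROBO2, summed over its circRNAs, had a log2 change of -1.73 (SE 0.371, adjusted p = 0.00579), with 4.75 for the circRNA sum and 6.47 for the mRNA. With circRNA totals made equal this call was lost, at -0.71 (adjusted p = 0.0950). The sum pools different circRNAs in each group. In control it is mostly those upstream of 77088930, which are listed at 0 in resistant libraries. The exonic circRNAs are near the floor in control, so no direction of the ratio is given for them. TBCD, a tubulin folding cofactor, had 2.51 to 2.62 RPM of circRNA in control and was listed at 0 in resistant libraries, while its mRNA rose (log2 ratio change -8.40), and the ratios of COMMD1, FBXL13, GCN1 and PPM1D also fell. The ratio rose by 6.71 for TROAP, whose mRNA fell by 4.29 on the log2 scale, and also for NAPB, TERF2IP, WWOX and AFF1. The circRNAs of TROAP, NAPB and TERF2IP were listed at 0 in each control library. Those of TBCD, COMMD1 and PPM1D were listed at 0 in each resistant library. The sizes of these ratio changes therefore depend on the pseudocount. Across hosts, circular and linear fold changes correlated at Pearson r = 0.405 and Spearman rho = 0.353, where hosts are not independent replicates.

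The miRNA comparison asked which miRNAs changed, with miR-625-5p the one in the title. Its 5p arm (MIR625, chromosome 14, 65471102 to 65471186) fell from 140 ± 9.95 CPM in control to 1 read over the 3 resistant libraries, a ratio of 2010-fold with a counting interval of 358 to 79607. Its 3p arm fell from 356 ± 14.3 CPM to 0 reads in each resistant library (log2 fold change -8.48). Of 520 miRNAs tested, 152 were higher and 308 lower in resistant cells (median log2 fold change -1.31), but 220 were higher and 241 lower after scaling to equal medians (median -0.17). The let-7 family, the miR-30 family and the other families below are therefore given with the counts from that scaling where they differ in direction. Mature miRNAs that differ by few bases, such as let-7 members and miR-376a and miR-376b, may share reads.

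The largest rises were miR-146a-5p, a brake on NF-kB signalling, which reached 75961 ± 9995 CPM (log2 fold change 11.62), and miR-155-5p, with 3 reads in control and 4021 to 4558 CPM in resistant cells, a ratio of 3728-fold with a counting interval of 1276 to 18079. The miRNAs miR-654-3p, miR-376a-3p, miR-381-3p, miR-487b-3p, miR-134-5p and miR-376b-3p, all of the 14q32 cluster, also rose, with 3821 ± 233 CPM of miR-654-3p in resistant cells and miR-487b-3p at least 253-fold higher. All 56 tested arms of that cluster (chromosome 14, 100814491 to 101066801) rose, with a median fitted log2 fold change of 7.03. No arm of the cluster reached 5 CPM in every control library. An arm could thus be tested only through the resistant libraries, and the filter set its direction. Untested arms stayed low in both groups, as miR-127-3p did at 1.67 CPM in control and 3.57 CPM in resistant libraries. The largest falls were miR-224-5p, from between 5979 and 6262 CPM to 3 reads over the resistant libraries, a ratio of 29359-fold with an interval of 10044 to 142380, and its neighbour miR-452-5p. Next to them miR-629-5p (1781 ± 32.1 CPM in control) was at least 2570-fold lower, miR-338-3p (1573 ± 116 CPM) at least 2269-fold, miR-4521 at least 1192-fold and miR-1269b at least 648-fold. The fall of miR-31-5p, encoded at 9p21, was from 585 ± 84.1 CPM to 1 read.

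Among the miRNA lists, 3 passed camera, or 2 at equal medians, and none kept its call with an estimated correlation. Of 10 splits of the libraries into 3 and 3, the real one included, 9 gave at least 3 lists. The number of lists thus does not set the real grouping apart. An arm under 5 CPM in each control library could be tested only through the resistant libraries, so the filter set its direction. The let-7 family had 12 arms higher and 3 lower of 19 (camera adjusted p = 0.0111, adjusted p = 0.357 with an estimated correlation), with miR-98-5p rising from 159 ± 33.4 to 1286 ± 171 CPM and let-7c-5p falling (log2 fold change -3.58). The clusters of miR-23, miR-24 and miR-27 had 8 higher and none lower of 9 (camera adjusted p = 0.0111, adjusted p = 0.357 with an estimated correlation), with miR-23b-3p rising from 1149 ± 48.3 to 2944 ± 327 CPM. Haematopoietic miRNAs had 6 higher and 1 lower of 7 (camera adjusted p = 0.0187, adjusted p = 0.515 with an estimated correlation), led by miR-146a and miR-155. These 7 came from 13 arms measured, and the filter set the direction of miR-155-5p and miR-146a-3p. The miR-200 family, which represses ZEB1 and ZEB2, had 5 higher and 4 lower of 9 (camera adjusted p = 0.290), and miR-200a-3p rose from 93.1 ± 23.5 to 5112 ± 898 CPM and miR-200b-3p from 10.9 ± 4.51 to 623 ± 110 CPM. The family of miR-34 and miR-449 had 4 higher and 2 lower of 7 (adjusted p = 0.261), with miR-34c-5p rising from 10.7, 1.12 and 0 CPM in the control libraries to 1800 ± 397 CPM, and the miR-29 family 4 higher and 3 lower of 7 (adjusted p = 0.261), or 4 higher and none lower at equal medians, with miR-29b-3p rising from 4538 ± 266 to 39027 ± 5648 CPM. The family of miR-192, miR-194 and miR-215 had 4 higher and none lower of 5 (adjusted p = 0.0560), with miR-194-5p rising (log2 fold change 1.77).

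The miR-17 to miR-92 and paralogue clusters had 19 arms lower and 2 higher of 22 (camera adjusted p = 0.0862), with miR-92a-3p falling from 13101 ± 828 to 430 ± 44.8 CPM. The HOX cluster miRNAs miR-10 and miR-196 had 8 lower and 1 higher of 10 (adjusted p = 0.261), with miR-196a-5p falling from 5429 ± 306 to 291 ± 13.7 CPM. Both miRNAs of the pair miR-221 and miR-222 were lower in all 4 tested arms (adjusted p = 0.265), and miR-221-3p fell from 11655 ± 1556 to 2406 ± 343 CPM. The family of miR-130 and miR-301 had 7 lower of 8 (adjusted p = 0.278), the stromal list of miR-143, miR-145, miR-199 and miR-214 5 lower of 5 (adjusted p = 0.278), with miR-199b-5p falling from 227 ± 54.6 to 8.03 ± 2.94 CPM, and the list of EGFR-inhibitor associated miRNAs 15 lower and 4 higher of 22 (adjusted p = 0.295), which holds miR-625 and miR-31. This last list had 12 lower and 9 higher at equal medians. At equal medians the lists of miR-130 and of miR-10 stayed mostly lower, with 5 lower and 1 higher and with 7 lower and 2 higher. The muscle, endothelial, neural and hepatic list had 3 higher and 4 lower of 7 (adjusted p = 0.820), with a median log2 fold change of -2.30 although camera gave the direction up, and the endothelial miR-126-3p fell from 19237 ± 1182 to 2885 ± 494 CPM. Both tested arms of the list of miR-224, miR-452 and the X-linked miR-506 to miR-514 cluster fell, too few for camera, and no arm of the list of the miR-371 to miR-373 and miR-302 clusters could be tested.

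For the other families the direction turned at equal medians, while quantile normalization turned it for the miR-30 family and the cluster of miR-183 only. The clusters of miR-99, miR-100 and miR-125 had 9 lower and 1 higher of 10 (adjusted p = 0.278) but 4 lower and 5 higher after scaling to equal medians and 5 lower and 1 higher after quantile normalization. In the unscaled CPM miR-99a-5p fell from 250 ± 38.2 to 1.15 ± 0.643 CPM, and it stayed lower under both scalings. The family of miR-15, miR-16, miR-195 and miR-497 had 10 lower and 1 higher of 15, and 9 lower adjusted over the list alone (adjusted p = 0.355), but 4 lower and 6 higher at equal medians and 9 lower and 2 higher after quantile normalization, with miR-16-5p falling from 139702 ± 4149 to 30201 ± 2914 CPM. The miR-30 family had 5 lower and 2 higher of 11, with 4 and 1 adjusted over the list alone (adjusted p = 0.66), but 1 lower and 8 higher at equal medians and 2 lower and 5 higher after quantile normalization, and camera gave the direction up against a median of -0.18. The miR-181 family had 4 lower and 1 higher of 10, with none higher adjusted over the list alone (adjusted p = 0.791), and 2 lower and 5 higher at equal medians but 4 lower and 1 higher after quantile normalization. The cluster of miR-183, miR-96 and miR-182 had 2 lower and 1 higher of 5 (adjusted p = 0.820), but 4 higher and none lower at equal medians and 3 higher and none lower after quantile normalization, with miR-182-5p at 5005 to 5342 CPM in control and 3519 ± 411 CPM in resistant cells.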

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

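Of the settings in this part and the report, other pseudocounts, equal medians, quantile normalization, equal circRNA totals, edgeR TMM on rebuilt reads with and without a block, the stricter filter on ratios and scaling without mitochondrially encoded genes were chosen after the data were seen. The cause of a difference was not tested unless the setting itself removes tests. At a 2-fold threshold 2566 mRNAs were higher and 3315 lower, and with at least 10 TPM, which tests fewer genes, 3874 were lower. No gene or miRNA list passed with an estimated correlation in camera (0 and 0), 21 and 17 passed fry, and 6 miRNA lists passed without a filter. Only 2 miRNA lists passed at equal medians, and 2 with TMM or RLE factors on rebuilt reads. With each library left out, 11 to 12 gene lists and 3 to 5 miRNA lists passed. The circRNA calls were 308 higher and 978 lower with at least 10 reads, 1016 and 852 after quantile normalization, 946 higher with equal totals, and 291 and 1442 summed per host. The circular-to-linear calls were 1024 with the stricter filter. Leaving out libraries gave 4521 to 4750 mRNAs higher and 5635 to 5926 lower, 558 to 624 circRNAs higher and 2512 to 2747 lower, up to 150 miRNAs higher and 297 to 305 lower, 1338 to 1500 ratios changed and a circRNA ratio of 0.434 to 0.515. The muscle, endothelial, neural and hepatic miRNA list turned down with fry (adjusted p = 0.000356), and 4 miRNAs turned from a negative to a positive log2 fold change with scaling. The cause was not tested. The values were, at equal medians, quantile, edgeR TMM, edgeR RLE and DESeq2, 0.12, 0.0632, 0.0446, 0.11 and 0.11 for hsa-miR-30b-3p, and 0.65, 0.25, 0.54, 0.61 and 0.61 for hsa-miR-182-5p. At equal medians, TMM, RLE, DESeq2 and voom they were 0.20, 0.10, 0.17, 0.17 and 0.0671 for hsa-miR-181c-5p, and 0.89, 0.78, 0.85, 0.85 and 0.78 for hsa-miR-183-5p. For hsa-miR-182-5p voom gave 0.54. All named genes kept direction and call except PDGFA, in 5 settings, and of the named circRNAs and hosts the lower ROBO2 circRNAs and the ROBO2 ratio lost their call in some.

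The libraries share replicate numbers only, and same-numbered libraries did not all correlate above 0.1 (r from -0.02 to 0.02 for mRNA, 0.03 to 0.04 for circRNA and -0.04 to 0.13 for miRNA). With a replicate block in limma, 4754 mRNAs were higher and 5852 lower, 629 and 2793 circRNAs, 152 and 313 miRNAs, and 1502 ratios changed. With the block in edgeR 322 circRNAs were higher and 947 lower, and the log2 fold changes were 0.0433 for hsa-miR-30b-3p, 0.0856 for hsa-miR-181c-5p, 0.54 for hsa-miR-182-5p and 0.78 for hsa-miR-183-5p. For the circRNA total the block, chosen after the data were seen, gave a mean paired ratio of 0.473 (exact sign-flip test, p = 0.25, the smallest that 3 pairs allow). Count tests of the mRNA table, circRNA scaled by mRNA counts and the interaction on counts were not run, because TPM holds no counts. Of 10 splits of the libraries into 3 and 3, only the real one gave as many calls, with 10749 mRNAs, 3378 circRNAs, 460 miRNAs and 1556 ratios against a highest other of 0 (1 split each), which are too few splits for a share under 0.05. Every other split mixes control and resistant libraries, so the difference between them becomes spread within its groups. A count near 0 there was to be foreseen and adds no support. For gene lists 2 splits gave as many as the real 12, and for miRNA lists 9 gave as many as the real 3, with 5 the highest.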

Other observations

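The genes in this paragraph were chosen after their values were seen. Of 85 genes near 0 in control that were high in resistant cells, 3 are given as examples. The sodium pump subunit FXYD2 stood at 123, 162 and 107 TPM in resistant libraries and SERPINA1 at 696, 803 and 535 TPM, both listed at 0 in control. The kidney injury marker HAVCR1 stood at 576, 519 and 570 TPM. A list of kidney tubule markers, written after these genes were seen, had 11 higher and 3 lower of 16 tested (camera p = 0.00219, p = 0.212 with an estimated correlation), among them the water channel AQP1 (log2 fold change 7.47) and PAX8 (4.50), with GATA3 lower. The list holds PDZK1IP1, itself one of the 85 genes. Members near 0 in control, such as PDZK1IP1, CDH16 and PAX8, passed the filter only through the resistant libraries, so their direction was fixed beforehand. The camera p is therefore no independent support for a kidney type.

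The genes in this paragraph, too, were chosen after their values were seen. Of ZNF genes with at least 2 TPM in control, 67 of 417 (16.1%) lay under 5% of control in resistant cells, against 5.57% of 11247 other genes. The reverse held for 4 of 269 ZNF genes (1.49%) and 5.03% of 10880 other genes. Among 78 ribosomal protein genes 61 changed, with a median log2 fold change of 0.21. As 81.5% of all tested genes changed, that count is not particular to them. RPL9 alone lay under 10% of control, while the largest rise was that of RPL22L1 (log2 fold change 2.98). The tumour suppressor CDKN2A, HTATIP2, the adhesion gene LSAMP and the transcription factor SOX4 were listed at 0 in each resistant library, with CDKN2A at 131 to 149 TPM in control.

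Of the tests on the patterns from here on, those on untranslated regions and on miR-625-5p sites were chosen before the result was seen, and the others after. The first pattern is the set of genes near 0 in resistant libraries, the 13 mitochondrially encoded mRNAs and 54 nuclear genes. Reads shared between annotated copies are not likely to account for the 7 mitochondrial mRNAs or the 32 nuclear genes with at least 0.9 unique 75-mers. The 6 other mitochondrial mRNAs had unique shares of 0.634 to 0.895 among annotated genes, and the highest stood at 0.181% of control. Loss of only the reads shared with annotated genes would leave their unique part, so these values argue against that loss for the 6. Unannotated copies are not covered, so sharing with those stays open. For the other nuclear genes shared reads stay open, with 62.7% of the nuclear set unique, against 90.1% of all genes at that level in control. Loss of mitochondrial DNA or its transcription may account for a median of 0.00540% of control, but nothing here tests it apart from other causes. A genome that differs from the reference could also lose reads, and its tests cannot tell either, with Spearman rho of -0.0948 between fold change and untranslated share and a difference of 0.0127 in that share for lost genes (permutation p = 0.763).

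The second pattern is a run of 13 neighbouring genes at 9p21 (chromosome 9, 20341665 to 27573866) from MLLT3 to C9orf72, with MTAP, CDKN2A and CDKN2B, listed at or near 0 in resistant libraries. Neighbours were counted among genes with a mean of at least 1 TPM in control. Chance adjacency is unlikely (permutation p = 0.0001 over 12456 genes, the smallest that 10000 shuffles allow). Of 20 circRNAs inside the run in control, 0 were found in a resistant library, but the run was picked for genes at 0, so this does not tell loss of the region from silencing or reads that do not map. MIR31 (chromosome 9, 21512115 to 21512185) also lies inside the run. In the separate miRNA assay miR-31-5p fell from 585 CPM in control to 1 read over the resistant libraries. That fall does not tell these causes apart either. A kidney-type origin of the resistant cells might bring such a difference, and the kidney list gave camera p = 0.00219 but p = 0.212 with an estimated correlation. That list was also written after the gained genes were seen and shares members with them, so this test cannot tell.

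The third pattern is the 55 miRNAs under 1% of control in resistant libraries, miR-625-3p and miR-31-5p among them. Lower depth cannot account for it, since the smallest resistant library had 4.24 times the reads of the largest control library. Loss was more frequent outside conserved families (45 of 127 against 10 of 172, odds ratio 8.82, 95% interval 4.12 to 20.7), as a genome that differs from the reference could bring, but the ratio for gained miRNAs, expected to be lower, was 13.1 (5.90 to 32.5) over all and 0.290 (0.00648 to 2.17) without the 14q32 cluster, so this stays open. Mitochondrial mRNAs near 0, lost ZNF genes and miRNAs, the 9p21 run and the gained kidney markers could together come from cells unrelated to the control, another species included, which would change what every fold change here means. No genome of another species was at hand, so no test here decides it.

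As a test of the axis in the title, genes with a miR-625-5p site in the 3' UTR were not shifted up, with a median shift of -0.01 that ranked 21 of 21 arrangements over 2257 genes. PDGFB has 2 such sites. In control miR-625-5p stood at only 140 CPM, and 81.5% of tested genes changed between libraries that may come from unrelated cells. A release of its targets could be hidden in such data, so this test neither backs nor excludes the axis.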
